A study of Mus musculus with 30 samples.

How the data were processed

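RNA-seq was read from 20 libraries: 3 pools of plated hepatocytes labelled A1cf-transgenic (Tg), 3 of wild-type hepatocytes, 4 of livers labelled Tg, 4 of wild-type C57BL/6J livers, 3 of A1cf-knockout livers and 3 of wild-type C57BL/6NJ livers. CLIP-seq, in which RNA is crosslinked by ultraviolet light to the protein that binds it and sequenced after the protein is precipitated, was read from 10 libraries of Tg hepatocytes. Per the labels, the authors called bases with bcl2fastq, aligned reads with STAR 2.0.4b to GRCm38 and assigned them to genes with featureCounts 1.45 of the Subread package. The labels used here do not give the strand setting, the annotation release, the treatment of reads that align more than once, or any removal of duplicate CLIP reads. The deposited tables give each of 41388 genes a raw read count, and this deposited count was the unit analysed. The deposited CPM values are the counts divided by the library total and multiplied by 1e6, and the largest difference on recomputation was 4.9e-10. The deposited RPKM values divide the deposited CPM further by gene length, with a largest difference of 5.1e-11; RPKM were not used here.

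Chromosomes and positions were checked against GENCODE M21, which holds 40340 of the identifiers, and 40244 overlapped their gene there. Gene names came from a separate list, which held 40254 of the identifiers, and otherwise from M21. Lengths are the deposited ones and were not checked. RNA-seq totals ran from 17044839 to 37211328 counts and CLIP totals from 6151 to 10902. A CLIP share of 0 therefore allows a true share of up to 0.0275% to 0.0488%, depending on the library, taking 3 counts as the limit. Intervals of shares are 95% Wilson binomial intervals. Intervals and limits cover counting error only, since reads copied by PCR are not independent molecules.

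Each of 3 comparisons was fitted on its own libraries: Tg against wild-type hepatocytes, Tg against C57BL/6J livers, and knockout against C57BL/6NJ livers. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood F-test in R 4.3.3. All p-values called adjusted are Benjamini-Hochberg values, with 0.05 as the threshold. All tests are two-sided, except that random draws, overlaps and Fisher's exact tests are one-sided. Fold changes are log2 estimates ± standard error (SE) from edgeR. Group levels are means ± standard deviation (SD) in TMM-scaled CPM, except that A1cf, sex-linked, substrain and muscle levels of single libraries are deposited CPM. A gene at 0 in every control library has no finite fold; it was compared with a floor of 3 counts over the control group. Differences between effects were tested as contrasts of 4 group means, as the Tg effect in liver minus that in hepatocytes and as the Tg effect minus the knockout effect in liver. Shared calls were counted beside the number chance gives, with Fisher's exact test over genes tested in both comparisons. Genes are not independent replicates, so p-values of Fisher's test can overstate the evidence. The labels do not pair replicates of equal number, the correlations of their deviations across genes ran from -0.705 to 0.812, and no block entered the fits.

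In all, 38 gene lists were written, of which 36 in hepatocytes and 37 in each liver comparison were tested by fry of limma 3.58.1, which asks whether the members move on balance in one direction, with Benjamini-Hochberg adjustment over the lists with at least 2 tested members. camera was run beside it, with a preset correlation of 0.01 and with a correlation estimated from the data. Members were counted over all genes tested and adjusted over the list alone. The comparisons, tests, lists and alternatives, and the rule for the genes to name, were fixed before the data were examined. The rule took A1cf. Per comparison it took the 10 largest rises and the 10 largest falls among genes at adjusted p below 0.05 with a mean of at least 2 CPM and no overlap between groups, passing over unnamed models. It also took up to 4 members with the smallest p of each list, the 6 genes with the smallest p of each interaction, the 10 shared genes with the largest smaller fold change, the 15 CLIP genes of highest share, the 10 of highest ratio over RNA, and Apob. Other genes, lists and features that are named were chosen after their values were seen, and they are identified as such. Some genes that the rule took are not reported here.

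CLIP libraries were described by the share of counts per gene and by detection in at least 5 libraries. They were also tested against the 3 Tg hepatocyte RNA pools with edgeR, where a gene at adjusted p below 0.05 and a log2 ratio of at least 1 was called enriched. The 200 protein-coding genes of highest CLIP share were tested as a list in the 3 comparisons, with 10000 random lists matched in expression beside them. No control precipitate is among the libraries, so CLIP values are levels and no measure of binding above background.

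The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter at 1 CPM, glmTreat with a fold of 1.2, a fit over all 6 RNA groups, the replicate number as a block, and leaving out each library in turn. The workflow was tested on simulated counts with known changes. They were drawn gene by gene from negative binomial distributions, with means and dispersions estimated from the real libraries. Shifts that real pools share across genes are absent from them. Scripts ran in R and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.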

Results

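The study measured RNA in livers and hepatocytes of mice labelled A1cf-transgenic (Tg), A1cf-knockout or wild-type, and the RNA recovered with A1CF from Tg hepatocytes. A1CF is an RNA-binding protein best known as a cofactor of APOBEC1, the cytidine deaminase that edits Apob mRNA. Hepatocytes came from 12-week-old mice and were plated overnight on collagen, 3 pools labelled Tg and 3 wild-type. Livers came from 12-month-old mice, with 4 Tg pools beside 4 wild-type C57BL/6J pools and 3 knockout pools beside 3 wild-type C57BL/6NJ pools. Each pool held RNA of 3 to 4 mice, so that p-values measure the spread between pools; the labels do not say whether pools share mice. Total counts per library were 26144213 to 37211328 for Tg hepatocytes, 33291216 to 36411146 for wild-type hepatocytes, 18308368 to 20711360 for Tg livers and 17044839 to 25315849 for their controls. They were 28753525 to 30600063 for knockout livers and 25888485 to 35365817 for their controls. The 10 CLIP libraries of Tg hepatocytes held 6151 to 10902 counts in 1043 to 1410 genes each, against 18559 to 22101 genes in the RNA libraries.

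A1cf itself (ENSMUSG00000052595, GRCm38 chromosome 19, 31868761 to 31949406) was strongly lower in knockout livers, slightly lower in livers labelled Tg, and near its control level in hepatocytes labelled Tg. Knockout livers held 24.5 ± 4.39 CPM (SD, n = 3) and C57BL/6NJ livers 213 ± 20.8 (n = 3), a log2 fold change of -3.12 ± 0.15 (SE) at an adjusted p of 1.59e-05. Tg livers held 163 ± 7.96 CPM (n = 4) and C57BL/6J livers 232 ± 30.9 (n = 4), a log2 fold change of -0.65 ± 0.11 at an adjusted p of 0.0369. Tg hepatocytes held 9.23 ± 1.64 CPM and wild-type hepatocytes 9.35 ± 2.51 (n = 3 each), with a log2 fold change of 0.02 ± 0.24 and an adjusted p of 0.962. That estimate was -0.04 without Tg hepatocyte pool 3 and -0.17 without wild-type pool 1. The fall in Tg livers lost its call without Tg pool 3 (adjusted p = 0.0934) or 4 (0.102), without wild-type pool 1 (0.0771), 3 (0.107) or 4 (0.099), and with replicate number as a block (0.108). Gene counts did not show a rise of A1cf in either set labelled Tg, and RNA made from a construct without the counted exons would not be seen in them.

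**Figure D1:**
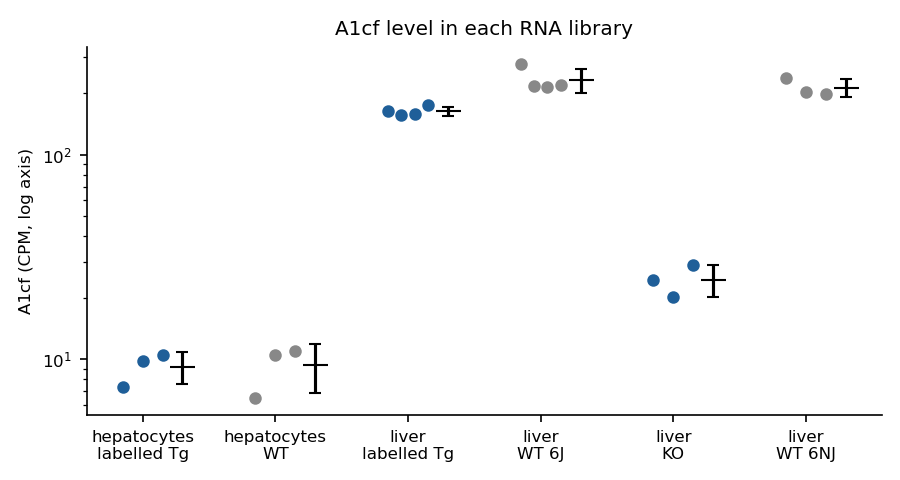
A1cf in each of the 20 RNA libraries, in deposited CPM on a log axis, by group; bars give the mean ± SD of each group. Knockout livers average 24.5 CPM against 213 in their controls, and the hepatocyte groups average 9.23 (Tg) and 9.35 (wild-type).

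The comparison of plated hepatocytes asked what changes in the liver's main cell type with the Tg label. Several genes known from fetal liver and liver tumours were higher in Tg hepatocytes. Some genes of fat storage and of the innate immune response were higher as well, while several major urinary protein genes, the phosphofructokinase genes Pfkp and Pfkl and genes of chromosome 14 were lower. Among genes with a mean of at least 2 CPM, the largest rise was that of Gldn (gliomedin, an adhesion protein of peripheral nerve, ENSMUSG00000046167, chromosome 9, 54286486 to 54341786), from 0.0637 ± 0.0569 to 11.1 ± 1.45 CPM (SD, n = 3 each), a log2 fold change of 7.32 ± 0.55 (adjusted p = 0.00582). Adgre5, the adhesion receptor CD97, rose from 3.73 ± 1.41 to 139 ± 37.4 CPM (5.22 ± 0.39, adjusted p = 0.00582). Ly6d, a surface protein of lymphoid and epithelial cells, rose from 4.03 ± 1.23 to 52.3 ± 3.27 CPM (3.70 ± 0.27, adjusted p = 0.00582). Cyp2a4, a female-biased P450, rose from 7.43 ± 3.81 to 121 ± 46.7 CPM (4.02 ± 0.49, adjusted p = 0.0167). Tspan15 (4.10), Krt23 (4.07), Chil1 (3.86), the collagen gene Col4a3 (3.69), the dicarboxylate carrier Slc13a3 (3.65) and the chemokine Cxcl14 (3.59) completed the 10 largest rises above that limit. Among the largest falls above it, Ndufa4l2, a hypoxia-induced mitochondrial protein, fell from 14.5 ± 3.82 to 1.45 ± 0.309 CPM (-3.33 ± 0.29, adjusted p = 0.00815). The others were Mup21 (-3.55), Mup12 (-2.97) and Mup1 (-2.97), which encode major urinary proteins, the chemokine receptor Ackr3 (-2.96), and the phosphofructokinase Pfkp (-2.75). Further falls were those of the transcription factor gene Sall2 (-2.70), the scaffold gene Grip1 (-2.54), Atg9b (-2.42) and the pyruvate dehydrogenase kinase Pdk1 (-2.26). In all, 434 of 13770 tested genes changed, 211 up and 223 down, and 184 and 139 of them by at least 2-fold. An unadjusted p below 0.05 was found for 3973 genes. The 3 Tg pools did not overlap the 3 wild-type pools in 4535 genes, 32.9% of those tested, where chance gives 10%. DESeq2 called 2027 genes, a fit over all 6 RNA groups 4323, and edgeR with replicate number as a block 21. Without Tg pools 1, 2 and 3 the count was 29, 12 and 4934. Without wild-type pools 1, 2 and 3 it was 44, 90 and 0 (2402 at an unadjusted p below 0.05, DESeq2 689), so that none of the 64 called genes under the naming rule passed in every such fit. Tg pools 1 and 2 and wild-type pool 1 stood apart from the other 3 pools, across the labels. Their log2 differences from the control mean fell with transcript length (r = -0.422, -0.354 and -0.32, against -0.167 in Tg pool 3 and 0.303 and 0.004 in wild-type pools 2 and 3). Mitochondrial RNA took 1.4%, 1.39% and 2.01% of their counts, against 3.48%, 3.71% and 3.14%. With 2 of these 3 pools labelled Tg, the difference is not balanced over the groups compared.

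The liver tumour and oncofetal list had the smallest fry p among the gene groups in Tg hepatocytes. Of its 25 tested members 8 rose, none fell and 17 did not pass (14 up and 2 down adjusted over the list alone), with a median log2 fold change of 1.13. fry gave an adjusted p of 0.00316, and the call was lost with an estimated correlation (adjusted p = 0.0975). They included the fetal serum protein Afp (1.71), the imprinted RNA H19 (4.22), the fetal mRNA-binding protein gene Igf2bp3 (2.45), the mucosal peptide Tff3 (3.50) and the desaturase Scd2 (2.82). H19 was near the floor, with 88 reads over all Tg pools against 5 over all wild-type pools. The adipocyte marker list was also called up by fry (adjusted p = 0.0215), but not with an estimated correlation (0.286): 3 of 6 members rose and none fell (4 up and 1 down adjusted over the list alone), with a median of 1.67. Its called members were the serine protease Cfd (5.56), the glycerol channel Aqp7 (3.16) and the lipid droplet protein Cidec (2.79). Cfd was low, with 364 reads over all Tg pools against 8 over all wild-type pools. Lipid droplet genes gave 3 rises and 1 fall among 17 (3 up and 2 down adjusted over the list alone, median 0.44, adjusted p = 0.0419, 0.286 with an estimated correlation). The fatty acid carrier Cd36 (2.54) and the acyltransferase Mogat1 (4.51, on 130 reads in Tg against 6 in wild-type pools) rose and Hsd17b13 (-0.83) fell. In fatty acid and triglyceride synthesis, 2 of 22 members rose and 1 fell (3 up and 5 down adjusted over the list alone, adjusted p = 0.686): Scd2 and Dgat2 (0.99), the last enzyme of triglyceride synthesis, rose, and the main hepatic desaturase Scd1 fell (-0.99). Pericentral genes, those expressed around the central vein, rose as a list (adjusted p = 0.00891, 0.286 with an estimated correlation), with 2 rises among 13, Slc1a2 (1.65) and Cyp2a5 (0.65), 6 up and 1 down adjusted over the list alone, and a median of 0.48.

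Several lists of immune cells and of the innate response were called up by fry in Tg hepatocytes, by small margins. Most of their members did not pass, and none of these lists was called with an estimated correlation. Inflammatory cytokines and chemokines gave 4 rises among 20 (10 up and 1 down adjusted over the list alone, median 0.97, adjusted p = 0.0439, 0.286 with an estimated correlation), with Ccl7 (2.26), Ccl3 (1.63), Tnf (1.36) and Cxcl1 (1.02). Interferon-stimulated genes gave 3 rises among 25 (9 up and none down adjusted over the list alone, median 0.42, adjusted p = 0.0451, 0.286 with an estimated correlation), all of the oligoadenylate synthetase family: Oas2 (2.00), Oas3 (1.54) and Oasl1 (1.28). Acute-phase genes gave 3 rises among 26 (9 up and 1 down adjusted over the list alone, median 0.21, adjusted p = 0.0352, 0.286 with an estimated correlation), namely Saa3 (1.76), Lrg1 (1.32) and Lbp (0.75). Antigen presentation (1 of 14 rose, Cd74 at 1.53, 3 up adjusted over the list alone, median 0.46, adjusted p = 0.0215, 0.286 with an estimated correlation) was called as well. So were T and NK cell markers (1 of 3, Ccl5 at 1.29, 1 up adjusted over the list alone, median 1.03, adjusted p = 0.0215, 0.286 with an estimated correlation) and B and plasma cell markers (1 of 4, Ighm at 3.01, 1 up adjusted over the list alone, median 0.89, adjusted p = 0.0352, 0.295 with an estimated correlation). Beside them, all 22 Kupffer cell and macrophage markers had estimates above 0, with a median of 0.85, 1 member past the threshold (Ly6c2, 2.53) and 3 up adjusted over the list alone, but the list was not called (adjusted p = 0.0648).

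Lists of stress responses, female-biased genes and clock genes were called by fry with few members past the threshold, and none was called with an estimated correlation. The unfolded protein response list gave 3 rises and 1 fall among 22 (5 up and 2 down adjusted over the list alone, median 0.27, adjusted p = 0.0352, 0.445 with an estimated correlation): Chac1 (1.42), Trib3 (1.2) and Ppp1r15a (0.81) of the integrated stress response rose, and the chaperone gene Dnajc3 (-1.26), on chromosome 14, fell. In the NRF2 and oxidative stress list, 2 of 18 rose, the quinone reductase Nqo1 (0.90) and the carbonyl reductase Cbr3 (1.21), with 5 up adjusted over the list alone, a median of 0.23 and an adjusted p of 0.0419 (0.329 with an estimated correlation). Female-biased liver genes rose as a list (2 of 19, Cyp2a4 and Cyp2b9 at 1.43, 3 up adjusted over the list alone, median 0.57, adjusted p = 0.0352, 0.286 with an estimated correlation). Male-biased genes had 4 falls among 22, all Mup genes, such as Mup7 (-2.04) and Mup3 (-1.53), with 2 up and 5 down adjusted over the list alone, but the list was not called (median -0.66, adjusted p = 0.32). The Y-linked genes were lower beside them without a call: Kdm5d went from 18.0 ± 2.95 to 7.77 ± 2.98 CPM (TMM-scaled, n = 3 each, -1.21, adjusted p = 0.0716) and was down adjusted over the list alone. Eif2s3y (-1.28), Uty (-1.41) and Ddx3y (-1.52) were not. Xist was not called either (0.21), and the sex chromosome list had a median of -1.28 (adjusted p = 0.114). Clock genes were lower as a list (median -0.29, adjusted p = 0.0352, 0.345 with an estimated correlation), with 0 of 19 past the threshold over all genes and 3 down adjusted over the list alone. The 3 tested genes that differ between the 6J and 6N substrains were lower as a list (median -0.77, adjusted p = 0.0451, 0.295 with an estimated correlation), and the 1 that fell was Ide (-1.43), which encodes the insulin-degrading enzyme. Of the 36 lists tested in hepatocytes, fry called 15, camera with the preset correlation 16, and camera with an estimated correlation 0 (4 at an unadjusted p below 0.05). Between 2 and 13 lists were called when 1 library was left out: 5, 6 and 13 without Tg pools 1, 2 and 3, and 3, 3 and 2 without wild-type pools 1, 2 and 3, where only the tumour and pericentral lists passed every time (highest adjusted p 0.0241 and 0.0377).

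Other groups in hepatocytes had few or no called members and were not called as lists. Single calls were the lipoprotein regulator Tm6sf2 (0.99) of 25 lipoprotein genes, the phosphofructokinase Pfkl (-1.19) of 19 genes of fructose and glucose metabolism, and Cyp2a5 and Cyp2b9 of 20 genes of xenobiotic metabolism. Further ones were Ccng1 (-0.87) of 18 p53 targets, the collagen-crosslinking enzyme gene Lox (-2.40) of 22 stellate cell and fibrosis genes, Pkhd1 (-1.14) of 12 cholangiocyte markers, Klf4 (2.28) of 18 immediate early genes and Hsd17b13 of 16 periportal genes. No member passed among 9 apoB mRNA editing factors (adjusted p = 0.114), 22 cholesterol synthesis genes (0.392), 30 PPARalpha targets (0.0902, 5 up adjusted over the list alone), 21 bile acid genes (0.427), 30 cell cycle genes (0.66), 18 liver endothelial markers (0.843), 5 red cell and platelet markers (0.0947), 20 hepatocyte markers (0.114) and 5 sex chromosome genes (0.114). Among 33 splicing factors and hnRNPs, 31 had estimates below 0, with a median of -0.67, none passed, and the list was not called (adjusted p = 0.114, 0.451 with an estimated correlation). Longer transcripts tended to lower fold changes across genes, which are not independent replicates (Spearman rho = -0.266), and the median length was 4457 bases for genes that fell against 3000 for those that rose. Neutrophil and exocrine pancreas markers had too few tested members here.

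Genes of chromosome 14, a feature chosen after the values were seen, were lower across the whole chromosome in every Tg hepatocyte pool. Of 437 tested genes there, 77 fell and 2 rose, against 13.8 changed genes by chance (Fisher's exact p = 3.13e-38), and 88.6% had estimates below 0, with a median of -0.69. camera gave an adjusted p of 0.0477 over the chromosomes with an estimated correlation. The genes that fell include Glud1, the mitochondrial glutamate dehydrogenase (from 757 ± 55.8 to 366 ± 52.9 CPM, n = 3 each), the transport protein gene Tm9sf2 (from 183 ± 5.30 to 81.6 ± 7.0), the tumour suppressor gene Rb1 (-1.70), the kinase gene Lats2 (-1.06) and Cpb2 (-0.93), the carboxypeptidase that slows fibrinolysis. Per library, the median log2 difference from the control mean over 327 genes was -0.80, -0.66 and -0.63 in Tg pools 1 to 3 and -0.04, 0.04 and 0.01 in the wild-type pools, and the exact permutation p was 0.1, the smallest that 3 against 3 allow. In Tg livers 9 of 467 genes on this chromosome fell and 4 rose (6.22 changed genes by chance, Fisher's exact p = 0.00982). In these livers camera with an estimated correlation did not call the chromosome (adjusted p = 0.745). The medians there were 0.01, -0.59, -0.38 and -0.31 in Tg pools 1 to 4 (exact permutation p = 0.143). Other chromosomes shifted in Tg livers too. Pools 3 and 4 moved alike on several, such as chromosomes 15 (0.239 and 0.146), 12 (-0.211 and -0.113), 18 (0.108 and 0.198) and 9 (-0.164 and -0.106), and chromosome 16 stood at -0.282 in pool 1 but at 0.121 and 0.123 in pools 3 and 4. The wild-type pools stayed within 0.031 of 0 on every chromosome. In Tg hepatocyte pools 1 and 2 other chromosomes moved too, the X by -0.456 and -0.349, while in pool 3 they stayed within 0.099 of 0. In knockout livers the median over 538 genes was -0.01, with 13 rises and 9 falls against 16.0 changes by chance. Without chromosome 14 genes, an alternative chosen after seeing the data, 283 genes were called in hepatocytes, 171 up and 112 down.

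**Figure D2:**
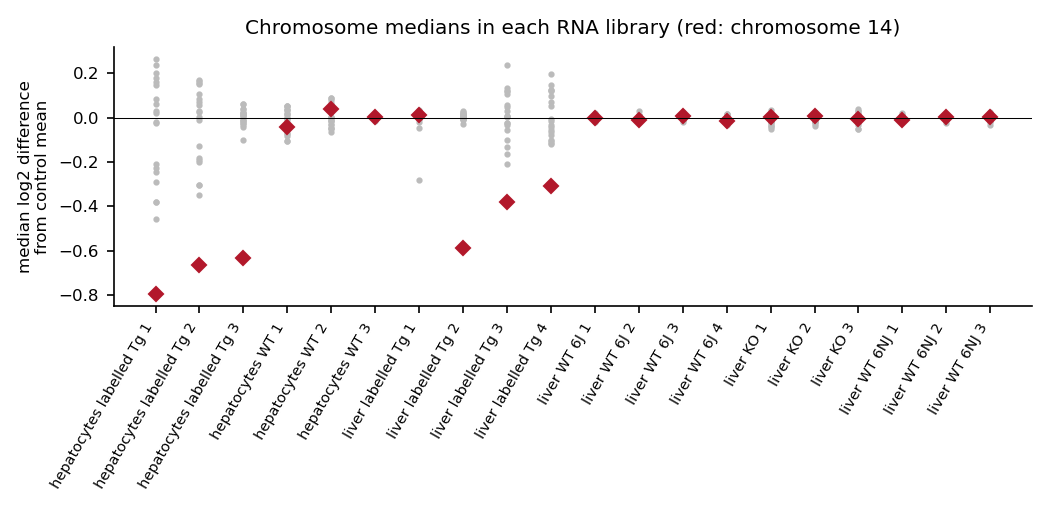
Median log2 difference of each RNA library from the mean of its controls, one point per chromosome, with chromosome 14 in red. Chromosome 14 stands at -0.80, -0.66 and -0.63 in the Tg hepatocyte pools and within 0.05 of 0 in the wild-type hepatocyte pools.

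The comparison of Tg livers with C57BL/6J livers addressed the effect of the label in whole tissue at 12 months. Tg livers held more RNA of the basement membrane collagens Col4a1 and Col4a2, of the p53 targets Cdkn1a and Eda2r and of several genes known from liver tumours, and less of Kyat3, Acot1 and Acot4. Gldn again rose, from 0.107 ± 0.107 to 14.4 ± 9.51 CPM (SD, n = 4 each, log2 fold change 6.99 ± 0.69, adjusted p = 0.00382). The largest fall among genes with a mean of at least 2 CPM was that of Kyat3, a kynurenine aminotransferase (ENSMUSG00000040213, chromosome 3, 142701051 to 142744910), from 174 ± 14.6 to 28.0 ± 7.91 CPM (-2.63 ± 0.19, adjusted p = 0.000779). Hsf2bp, a meiotic recombination factor, rose from 0.236 ± 0.112 to 5.62 ± 1.23 CPM (4.57 ± 0.35, adjusted p = 0.000867). Ly6d rose with a wide spread, from 1.15 ± 0.486 to 85.3 ± 99.2 CPM (6.16 ± 1.05, adjusted p = 0.0349). The other large rises above that limit were those of Mup-ps20 (7.26), the angiotensin-(1-7) receptor gene Mas1 (5.15), the dynein gene Dnah1 (5.00), Lrtm2 (4.58), Mup9 (4.44), Tff3 (4.39) and Gipc2 (4.26). The macrophage scavenger receptor gene Cd163 fell from 30.2 ± 7.21 to 10.1 ± 4.05 CPM (-1.58 ± 0.28, adjusted p = 0.037). Dmrta1 (-2.30), the acyl-CoA thioesterases Acot4 (-2.10) and Acot1 (-1.80), the junctophilin gene Jph1 (-1.75), the muscle protein gene Xirp1 (-1.56), Zc3h8 (-1.27) and the scaffold gene Homer2 (-1.15) were among the largest falls above it. In all, 188 of 14110 tested genes changed, 137 up and 51 down, 116 and 21 of them by at least 2-fold, and 2861 had an unadjusted p below 0.05. Wild-type pool 2 held 935 CPM of Xist, the RNA of the inactive X chromosome of females, against 5.51 or less in the 19 other libraries, and 778 CPM of the skeletal muscle actin gene Acta1. Without this pool 385 genes were called, 296 up and 89 down, 165 of them among the 188, and Mup9, Tff3, Gipc2 and Lrg1 lost their calls. The count was 561, 371, 56 and 35 without Tg pools 1 to 4 and 44, 27 and 29 without wild-type pools 1, 3 and 4. Of the 38 called genes under the naming rule, Asns, Col4a2, Gldn, Homer2, Hsf2bp, Kyat3 and S100a11 passed in every such fit. DESeq2 called 1242 genes, limma-voom 96 and edgeR with replicate number as a block 44.

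By gene group, p53 targets were called up in Tg livers by fry (adjusted p = 0.0132), but not with an estimated correlation (0.118): 2 of 17 members rose, none fell, and 5 were up adjusted over the list alone, with a median log2 fold change of 0.36. The called ones were the cell cycle inhibitor gene Cdkn1a, from 2.88 ± 0.914 to 24.0 ± 15.0 CPM (n = 4 each, 3.04 ± 0.49, adjusted p = 0.032), and the death receptor gene Eda2r (2.27). The adipocyte marker list was called up by fry as well (median 1.80, adjusted p = 0.0243), but not with an estimated correlation (0.16), with 0 of 6 members past the threshold over all genes and 5 up adjusted over the list alone, such as Cidec at 2.07 (adjusted p = 0.0611 over all genes). Without 1 library the p53 list lost its call only without Tg pool 4 (adjusted p = 0.0574), and the adipocyte list lost it without Tg pool 3 (0.0761) or 4 (0.0878) and wild-type pool 1 (0.0777), 3 (0.081) or 4 (0.0976). In those fits 9, 3, 1 and 0 lists were called without Tg pools 1 to 4 and 1, 8, 1 and 1 without wild-type pools 1 to 4. camera called 25 lists with the preset correlation and 0 with an estimated one (5 at an unadjusted p below 0.05), and fry had 17 at an unadjusted p below 0.05.

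Stellate cell and fibrosis genes were the largest group of single calls in Tg livers: 6 of 30 rose, none fell and 24 were up adjusted over the list alone (median 0.86), with a list p that missed the threshold (adjusted p = 0.0545, 0.286 with an estimated correlation). Col4a2 rose from 42.1 ± 2.44 to 133 ± 33.5 CPM (n = 4 each, 1.66 ± 0.17, adjusted p = 0.00435), and Col4a1 (1.49), Ccn2 (1.12) and the platelet-derived growth factor receptor gene Pdgfrb (0.86) rose with it. In the tumour and oncofetal list 4 of 26 rose, none fell and 14 were up adjusted over the list alone (median 1.25, adjusted p = 0.0839, 0.301 with an estimated correlation): Ly6d, Tff3, Scd2 (3.68) and the calcium-binding protein gene S100a11 (2.47). Among cell cycle genes 2 of 27 rose and 19 were up adjusted over the list alone (median 1.40, adjusted p = 0.0839, 0.302 with an estimated correlation), the called ones being the helicase subunits Mcm2 (1.03) and Mcm6 (1.22). Kupffer cell and macrophage markers gave 1 rise, Mpeg1 (1.15), and 1 fall, Cd163, among 24 (17 up and 2 down adjusted over the list alone, median 0.92, adjusted p = 0.084). Clock genes gave 2 falls among 19, including Cry1 (-0.999), with 3 up and 11 down adjusted over the list alone (median -0.63, adjusted p = 0.0695, 0.301 with an estimated correlation). The stress gene Asns, which encodes asparagine synthetase, rose from 0.543 ± 0.211 to 5.37 ± 2.02 CPM (3.27 ± 0.38, adjusted p = 0.00771) and was the 1 call among 22 unfolded protein response genes (adjusted p = 0.997). All 22 cholesterol synthesis genes had estimates below 0, with a median of -0.55; none passed over all genes, 2 were down adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0899, 0.302 with an estimated correlation). All 18 NRF2 and oxidative stress genes had estimates above 0, with a median of 0.73, 4 up adjusted over the list alone and an adjusted p of 0.167.

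Further groups in Tg livers held single calls or none. A1cf was the 1 fall among 9 apoB mRNA editing factors (adjusted p = 0.19), the HDL receptor gene Scarb1 (0.56) the 1 rise among 25 lipoprotein genes (0.0899), Scd2 that among 22 genes of fatty acid and triglyceride synthesis (0.161), Cd4 (1.99) that among 9 T and NK cell markers (0.564) and Lrg1 (1.17) that among 26 acute-phase genes (0.39). Acot1 and Acot4 were the 2 falls among 30 PPARalpha targets (0.135). No member passed among 17 lipid droplet genes (0.472), 19 genes of fructose and glucose metabolism (0.084, 6 down adjusted over the list alone), 21 bile acid genes (0.084), 20 xenobiotic genes (0.084), 4 neutrophil markers (0.0949), 10 B and plasma cell markers (0.564), 18 liver endothelial markers (0.43), 13 cholangiocyte markers (0.141), 8 red cell and platelet markers (0.904) and 20 hepatocyte markers (0.084). Among the last, Alb, the gene of albumin, stood at 44435 ± 4332 CPM against 80036 ± 3903 (-0.85, adjusted p = 0.0544). Nor did any member pass among 25 interferon-stimulated genes (0.287), 14 antigen presentation genes (0.084, 7 up adjusted over the list alone), 13 inflammatory genes (0.084, 6 up adjusted over the list alone), 17 immediate early genes (0.819), 16 pericentral genes (0.819), 16 periportal genes (0.472), 33 splicing factors and hnRNPs (0.0545), 22 male-biased genes (0.494) and 3 substrain genes (0.754). The 19 female-biased genes had a median of -2.50 and the 5 sex chromosome genes a median of -0.31 and a mean of -1.45, while fry put the latter up; neither list was called (0.564 and 0.904), and both contain genes that wild-type pool 2 sets apart.

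Calls shared by both Tg comparisons were more than chance gives. Of 12682 genes tested in both, 25 rose in both (1.67 by chance, Fisher's exact p = 8.17e-23) and 6 fell in both (0.787, p = 0.000124). The test takes each gene as independent, so these p-values can overstate the evidence. Only 1, the unnamed model Gm17767, went opposite ways (-2.44 in hepatocytes, 1.92 in liver). The shared rises included Gldn, Ly6d, the transcription factor gene Sall4 (4.97 in hepatocytes, 5.21 in liver), Mas1 (4.397, 5.15) and the carrier gene Slc35f2 (3.401, 3.76). Mup9 (3.37, 4.44), Tff3, Scd2 and the protease gene Tmprss4 (5.08, 2.76) were also among them. The shared falls, named after their values were seen where the rule did not take them, were Kyat3 (-1.13, -2.63), Pdk1 (-2.26, -0.99), Pcca (-0.95, -0.93), Cdadc1, Ndrg2 and Mxi1. Of these, Pcca, Cdadc1 and Ndrg2 lie on chromosome 14, where most genes were lower in Tg samples. Without the genes of that chromosome, an alternative chosen after seeing the data, 3 fell in both (0.422 by chance, p = 0.00851) and 25 rose (1.66, p = 6.66e-23). Across these genes, which are not independent replicates, the fold changes had a Pearson r of 0.312 and a Spearman rho of 0.299. Without wild-type liver pool 2, an alternative chosen after seeing the data, 40 genes moved the same way in both.

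**Figure D3:**
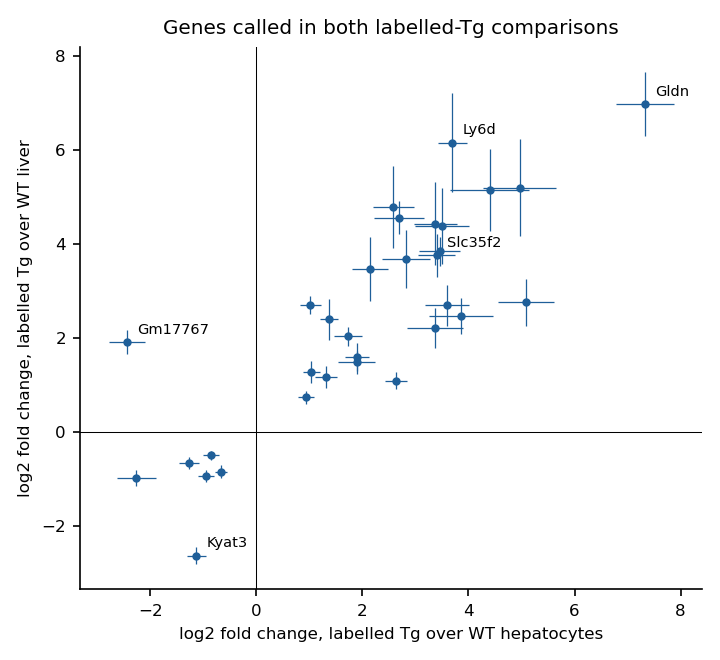
Log2 fold change (Tg over wild-type) in liver against that in hepatocytes for the genes called in both comparisons, with bars of 1 SE on each axis. Of the 32 genes, 25 rose in both and 6 fell in both; Gm17767 is the exception.

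The contrast of the Tg effect in liver with that in hepatocytes differed for 131 of 15565 genes, 61 higher and 70 lower in liver (3551 at an unadjusted p below 0.05). With upper-quartile scaling 129 differed, 81 higher and 48 lower. Adgre5 had the smallest p (log2 difference -4.65 ± 0.42, adjusted p = 0.000347), with 0.77 in liver against 5.22 in hepatocytes, followed by Ndufa4l2 (3.71, 0.57 against -3.33), the proteoglycan gene Prelp (-1.70, 0.43 against 1.95), the ficolin gene Fcna (-1.64, -0.44 against 1.02), Cpne8 (1.93, 1.42 against -0.69) and Pfkp (3.21, 0.66 against -2.75). Tissue, age, plating and sequencing study all differ between the arms and cannot be told apart. DESeq2 counted 968 genes and edgeR with replicate number as a block 18. Without Tg hepatocyte pools 1, 2 and 3 the count was 10, 5 and 3545, without wild-type hepatocyte pools 1, 2 and 3 it was 86, 70 and 13. Without Tg liver pools 1 to 4 it was 141, 232, 78 and 22, and without wild-type liver pools 1 to 4 it was 53, 119, 22 and 17.

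The comparison of knockout with C57BL/6NJ livers addressed the loss of A1cf. Knockout livers held less RNA of 11 of 22 cholesterol synthesis genes, of asparagine synthetase and of the imprinted RNAs Meg3 and Rian, and more of 10 of 30 PPARalpha targets, of the adipocyte protease Cfd (adipsin), and of skeletal muscle genes. Asns fell from 9.35 ± 6.57 to 0.202 ± 0.00603 CPM (SD, n = 3 each, log2 fold change -5.51 ± 0.67, adjusted p = 0.00351). Meg3 fell from 11.3 ± 1.85 to 2.43 ± 0.746 CPM (-2.21 ± 0.23, adjusted p = 0.00115), and Rian, from the same imprinted region of chromosome 12, fell with it (-2.77). Among genes with a mean of at least 2 CPM, the other large falls, besides A1cf, were those of the energy homeostasis gene Enho (-3.63), the mannosyltransferase gene Dpy19l3 (-2.38), Adgrf1 (-2.23), the calpain gene Capn8 (-2.07), the presynaptic protein gene Pclo (-1.96) and the water channel gene Aqp4 (-1.93). Cfd rose from 2.47 ± 0.579 to 120 ± 48.0 CPM (5.59 ± 0.32, adjusted p = 4.97e-05), and En2, a homeobox gene of the midbrain, from 0.294 ± 0.107 to 13.4 ± 2.88 CPM (5.49 ± 0.27, adjusted p = 1.59e-05). The remaining large rises above that limit were all of skeletal muscle: Acta1 rose from 0.0487 ± 0.0455 to 29.2 ± 18.9 CPM (9.01 ± 0.91, adjusted p = 0.001), and the myosins Myh2 and Myh4 and myoglobin (Mb), with no read in any control library, stood at least 381-fold, 211-fold and 171-fold higher over the pooled counts of the 3 knockout pools. The pools differed widely, with Myh4 at 0.817, 3.48 and 15.8 CPM, and with 1 library out Myh4 passed in 2 of 6 fits, Mb in 3, Myh1 in 4 and Ckm in 5. Myh1 had 1022 counts against 2, the troponins Tnnt3 571 against 1 and Tnni2 372 against 3, and the creatine kinase gene Ckm 487 against 5. All of these muscle genes were far higher in wild-type C57BL/6J liver pool 2, with Acta1 at 777.6 and Myh2 at 247.4 deposited CPM. Muscle tissue taken along with the liver was thus not told apart from an effect of the knockout. In all, 475 of 15942 tested genes changed, 239 up and 236 down, 124 and 68 of them by at least 2-fold, and 2941 had an unadjusted p below 0.05. The groups did not overlap in 3879 genes, 24.3% of those tested, where chance gives 10%. DESeq2 called 892 genes and the fit over all 6 RNA groups 42. The count was 137, 293 and 185 without knockout pools 1, 2 and 3 and 645, 193 and 293 without control pools 1, 2 and 3. Acta1, Asns, A1cf, Cfd, En2, Meg3, Rian and Myh2 were among the 29 of 61 called genes under the naming rule that passed in every such fit.

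Cholesterol synthesis showed the most uniform change in knockout livers: 11 of 22 members fell, none rose, 20 were down adjusted over the list alone, and all 22 estimates were below 0, with a median of -0.88. Hmgcs1, the cytosolic synthase at the pathway's entry, fell from 298 ± 17.2 to 101 ± 13.2 CPM (SD, n = 3 each, log2 fold change -1.57 ± 0.11, adjusted p = 0.000179). Idi1, the isopentenyl diphosphate isomerase, fell from 43.7 ± 6.74 to 12.3 ± 1.99 (-1.83 ± 0.15, adjusted p = 0.000266), and the demethylase Cyp51 from 178 ± 20.5 to 63.9 ± 9.78 (-1.48 ± 0.13, adjusted p = 0.000474). fry missed the threshold for the list over all lists (p = 0.00323, adjusted p = 0.0705), as did camera with an estimated correlation (adjusted p = 0.304). PPARalpha targets and fatty acid oxidation genes gave 10 rises and 1 fall among 30 (20 up and 2 down adjusted over the list alone, median 0.30, adjusted p = 0.0705, 0.304 with an estimated correlation). The thioesterases Acot1 (1.62) and Acot2 (1.32), the fatty acid hydroxylase Cyp4a10 (from 371 ± 36.1 to 1211 ± 507 CPM) and the pantetheinase Vnn1 (1.29) rose, and the hormone gene Fgf21 (-1.80), outside the naming rule and chosen after its value was seen, fell. Lipid droplet genes gave 4 rises among 17 (5 up and 2 down adjusted over the list alone, adjusted p = 0.362): Plin4 (1.09), the adipogenic receptor gene Pparg (0.86), Cd36 (0.67) and Cidea (2.22). Periportal genes gave 4 falls and 1 rise among 16 (adjusted p = 0.0705, 0.304 with an estimated correlation): the urea cycle enzymes Cps1 (-0.66), Ass1 (-0.71) and Arg1 (-0.43, outside the naming rule and chosen after its value was seen) and the cadherin gene Cdh1 (-1.20) fell, and the gluconeogenic enzyme gene Pck1 (0.56) rose. Of the 37 lists tested, fry called 0. Of these, 9 had an unadjusted p below 0.05, and camera called 15 with the preset correlation and 0 with an estimated one (5 at an unadjusted p below 0.05).

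**Figure D4:**
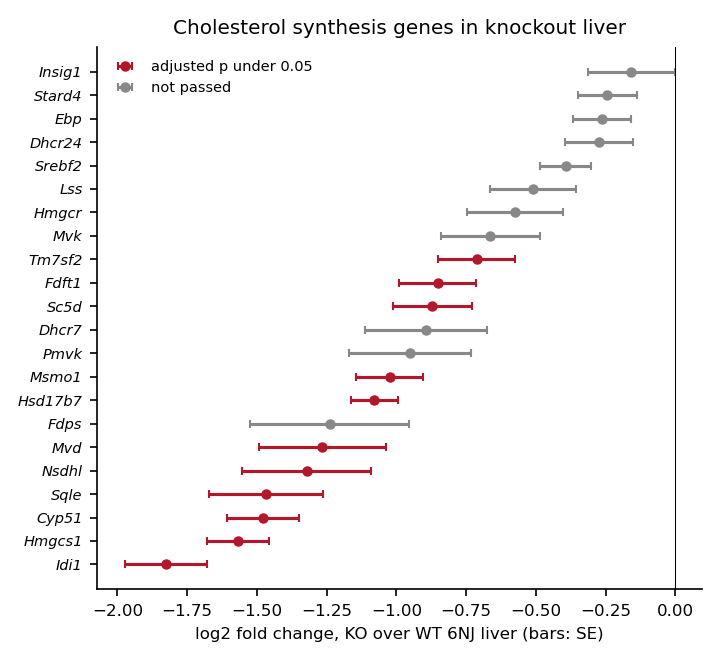
Log2 fold change (knockout over wild-type) of the 22 cholesterol synthesis genes in liver, with bars of 1 SE; red marks an adjusted p below 0.05. All 22 lie below 0, and 11 passed the test.

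Several smaller groups held calls in knockout livers without a list call. Adipocyte markers gave 2 rises, Cfd and the lipase gene Lipe (0.88), and 1 fall, the receptor gene Adrb3 (-1.19), among 5 (adjusted p = 0.0987, 0.304 with an estimated correlation). Stellate cell and fibrosis genes gave 2 rises among 31, Col4a2 (0.85) and the macrophage elastase gene Mmp12 (1.55), with 18 up and 3 down adjusted over the list alone (adjusted p = 0.0797, 0.304 with an estimated correlation). Immediate early genes gave 2 rises among 18, Egr1 (1.04) and Atf3 (1.29) (adjusted p = 0.0777, 0.304 with an estimated correlation). Of 9 apoB mRNA editing factors A1cf fell and Rbm47 (0.53), another RNA-binding cofactor of Apob editing, rose (median 0.02, mean -0.30, and fry down, adjusted p = 0.0705). Male-biased genes gave 2 rises, Mup20 (from 1024 ± 192 to 3522 ± 157 CPM) and Mup21 (1.70), and 1 fall, Cyp7b1 (-1.21), among 23 (adjusted p = 0.391). Female-biased genes gave 3 falls among 21: the receptor gene Ntrk2 (-2.48), the carrier gene Slc22a27 (-2.94) and the oxidase gene Hao2 (-4.33) (adjusted p = 0.232). Bile acid genes gave 1 rise, Slco1a4 (0.86), and 2 falls, the export pump gene Abcb11 (-0.52) and Cyp7b1, among 20 (adjusted p = 0.501). Lipoprotein genes gave 1 rise, Apoc2 (0.73), and 1 fall, Pltp (-0.93), among 25 (0.642). Unfolded protein response genes gave 1 rise, Atf3, and 2 falls, Asns and Edem1 (-0.47), among 22 (0.413), and tumour and oncofetal genes 2 rises, H19 (3.35) and Cbr3 (1.56), among 25 (0.696).

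The other lists in knockout livers held at most 2 calls. Single falls were those of Fasn (-0.72), the fatty acid synthase, among 22 synthesis genes (adjusted p = 0.642), Igkc (-1.59) among 12 B and plasma cell markers (0.28), Lect2 (-1.19) among 16 pericentral genes (0.28) and Ciart (-0.86) among 18 clock genes (0.642). Cps1 and Ass1 were the 2 falls among 20 hepatocyte markers (0.157). Single rises were those of Pck1 among 19 genes of fructose and glucose metabolism (0.911) and Cbr3 among 19 NRF2 genes (0.887). No member passed among 25 interferon-stimulated genes, of which 21 had estimates above 0 (adjusted p = 0.0705, 0.304 with an estimated correlation), 20 xenobiotic genes (0.753), 18 p53 targets (0.6), 27 cell cycle genes (0.887), 24 Kupffer cell markers (0.887), 5 neutrophil markers (0.391), 12 T and NK cell markers (0.642), 18 endothelial markers (0.186), 12 cholangiocyte markers (0.753) and 9 red cell and platelet markers (0.694). The same held for 26 acute-phase genes (0.642), 14 antigen presentation genes (0.902), 12 inflammatory genes (0.642), 5 sex chromosome genes (0.6), 34 splicing factors and hnRNPs (0.642) and 4 substrain genes (0.753). Of the exocrine pancreas markers, only Cela1 was tested (-0.77, adjusted p = 0.0193), which is too few for a list.

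Knockout calls shared few genes with the Tg calls, though the shared rises were more than chance gives. Of 13003 genes tested in both, 11 rose in Tg hepatocytes and in knockout livers (2.57 by chance, Fisher's exact p = 5.53e-05). Among them were Cfd (5.56 and 5.59) and H19 (4.22 and 3.35, at means of only 0.945 and 1.86 deposited CPM). There 6 fell in both (3.7, p = 0.167), such as Maoa (-1.21 and -0.95), and 5 fell in hepatocytes and rose in knockout livers (3.18, p = 0.213), such as Mup21 (-3.55 and 1.70). Of 13870 genes tested in both liver comparisons, 6 rose in both (1.71, p = 0.00741), such as Lrtm2 (4.58 and 3.75) and Col4a2, and 3, A1cf, Kyat3 and Xirp1, fell in both (0.842, p = 0.0519). Acot1 was 1 of 3 genes that fell in Tg and rose in knockout livers (-1.80 and 1.62, 0.721 by chance, p = 0.0353), and Asns was the 1 gene that rose in Tg and fell in knockout livers (3.27 and -5.51, 2.00 by chance, p = 0.868). Without wild-type liver pool 2, the liver comparisons shared 18 genes in the same direction and 9 in opposite ones, against 9 and 4 with it. Tested as a difference of effects, 167 of 16295 genes differed between the Tg and knockout effects in liver, 100 higher and 67 lower with Tg (2758 at an unadjusted p below 0.05). The first 6 were A1cf (2.46, adjusted p = 8.17e-05), Asns (8.76, 0.000166), Meg3 (5.04, 0.000435), Acot1 (-3.43, 0.000435), Ccdc171 (2.48, 0.000863) and En2 (-8.74, 0.000874). Meg3 and En2 were too low to be tested in the Tg liver comparison, so their differences lean on low counts there. They averaged 0.748 and 0.0262 deposited CPM in Tg livers and 0.0957 and 0.246 in C57BL/6J livers. Asns averaged 0.517 in C57BL/6J and 9.28 in C57BL/6NJ livers, so its 2 control groups differ as well. Where so few genes are shared, they were named after their values were seen. The liver comparisons share no controls, and substrain and sequencing study cannot be told apart from genotype. DESeq2 counted 796 genes and edgeR with replicate number as a block 58. Without Tg liver pools 1 to 4 the count was 449, 395, 90 and 65, without wild-type pools 1 to 4 it was 120, 314, 77 and 85. Without knockout pools 1 to 3 it was 24, 50 and 46, and without C57BL/6NJ pools 1 to 3 it was 205, 37 and 36.

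CLIP of Tg hepatocytes asked which RNAs A1CF binds. Its counts were concentrated on few genes, and the 10 libraries fell into 2 sets with different genes at the top. In libraries 1, 3, 4, 6 and 10, Itpripl2 took 10.5% to 14.5% of the counts and the noncoding RNA Pantr1 0.114% to 0.302%; in libraries 2, 5, 7, 8 and 9, Pantr1 took 15.9% to 18.5% and Itpripl2 0 to 0.0555%. The log2 shares correlated across genes, which are not independent replicates, at r = 0.702 to 0.844 over the 20 pairs of libraries within a set and at -0.145 to -0.022 over the 25 pairs between sets. The 6 genes that followed in the mean over all libraries each had nearly all of their counts in 1 set, so that their mean describes neither. In the set of Itpripl2, Fignl2 took 9.70% to 10.7%, the transcription factor gene Zfhx3 7.45% to 11.7%, the galactosyltransferase gene Ggta1 7.72% to 9.73% and the endothelial nitric oxide synthase Nos3 5.14% to 5.81%. The highest shares of these genes in the other set were 0.0438%, 0.347%, 0.0290% and 0. In the set of Pantr1, the ligand gene Wnt11 took 10.3% to 11.6% and the malic enzyme Me1 3.05% to 6.15%, against at most 0.111% and 0.0610% in the other set. Myh7b, Grin3b, Fzd10, Ppia, Eif2ak3, Acvrl1 and Zdhhc22 were also among the 15 protein-coding genes of highest mean share. A few genes were seen in all 10 libraries with shares that overlapped between the sets. Among them were the palmitoyltransferase gene Zdhhc22 (1.28% ± 0.266), the teneurin gene Tenm2 (1.11% ± 0.158), the glycosyltransferase gene A4gnt (0.503% ± 0.199, from 0.274% to 0.888%) and Gm26688 (0.506% ± 0.112). Their RNA was nearly absent from Tg hepatocytes, at means of 0, 0.00896, 0.0102 and 0.0128 deposited CPM in that order (n = 3). Apob, the classical target of A1CF, had 2 reads over all libraries, in libraries 4 and 6, while its RNA stood at 1479 ± 1454 deposited CPM in Tg hepatocytes (n = 3). A1cf had 0 reads. In all, 646 genes had a read in at least 5 libraries, 591 of them protein-coding, and they took 86.1% of the counts.

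**Figure D5:**
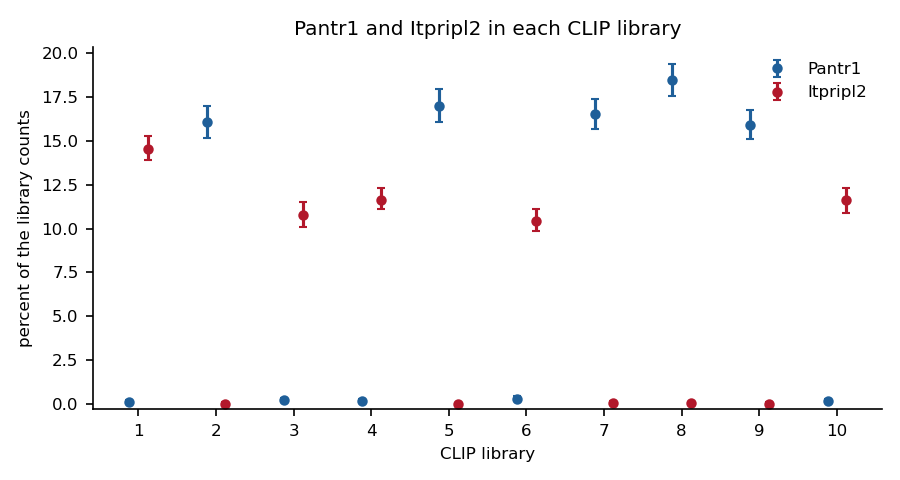
Share of CLIP counts (%) taken by Pantr1 and Itpripl2 in each of the 10 CLIP libraries, with 95% binomial intervals. Pantr1 takes 15.9% to 18.5% in libraries 2, 5, 7, 8 and 9, and Itpripl2 10.5% to 14.5% in the others.

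CLIP shares did not follow RNA levels. Across the 591 protein-coding genes, which are not independent replicates, Spearman's rho with the RNA level in Tg hepatocytes was -0.02, and 64 of the 200 genes of highest share had RNA below 1 CPM. Ranked within each set, a test chosen after seeing the data, rho was -0.01 over 599 genes in the set of Itpripl2 and -0.0005 over 631 in that of Pantr1. There 67 and 70 of the 200 highest had RNA below 1 CPM, and the 2 lists of 200 shared 71 genes. Of 152 genes tested, 33 were enriched over RNA and 64 were lower (100 at an unadjusted p below 0.05). The 10 highest were Pantr1, Zdhhc22, Tenm2, the forkhead gene Foxd1, the ceramidase gene Acer1, A4gnt, the Wnt receptor gene Fzd10, Gm26688, Myh7b and 1700104B16Rik, of which Pantr1, Zdhhc22, Foxd1, Acer1 and 1700104B16Rik had no read in the RNA pools. The assay and its library method differ together with binding, so the ratio ranks genes and is no measure of binding. With CLIP totals this small, the filter's minimum count of 10 kept only genes at a high level in several libraries of either assay. The tested genes were thus high in CLIP or in RNA from the start. The counts of enriched and lower genes are largely set by that filter. The ranking pools the 2 unlike sets of libraries, and genes without an RNA read have no finite ratio behind their place. With total-count scaling 79 genes were enriched, and without Tg hepatocyte RNA pool 1 it was 18. In the hepatocyte comparison the 200 genes of highest CLIP share were slightly lower on balance (149 tested, median -0.07, fry p = 0.011, adjusted over the 3 comparisons p = 0.033), but camera gave p = 0.282 with the preset correlation and p = 0.167 with an estimated correlation. Of these 149 genes 2 rose, the C/EBP transcription factor gene Cebpd (1.60) and Lysmd2 (0.91), and 1 fell, the membrane linker moesin Msn (-0.89), all chosen after their values were seen; 2 were up and 12 down adjusted over the list alone. The median lay at percentile 12.8 of random lists matched in expression, but not in chromosome or transcript length. The lower chromosome 14 genes and the length trend of the hepatocyte pools were thus not set apart from the CLIP list. The 500 highest gave fry p = 0.0399 (adjusted p = 0.12), and the 200 highest ranked within the sets of Itpripl2 and Pantr1 gave 0.0214 (0.0642) and 0.0363 (0.109), so the call was lost in each of these lists, with the direction kept. In Tg livers the list's median was -0.03 (148 tested, 2 fell, Dmrta1 and Dlgap1 at -0.95, fry p = 0.675). In knockout livers it was 0.01 while fry put the list down (158 tested, 1 rose, Oplah, and 3 fell, Ppl, Cdh1 and Hccs, fry p = 0.65). Dlgap1, Oplah, Ppl and Hccs were likewise chosen after their values were seen.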

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

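The tests of explanations and the counts of other splits given in this part were chosen only after the results were seen; the tests of differences between effects were planned. Of 80 groups of 4 to 10 values examined, 11 held a value far from the others of its group, and chance gives about 1 in 20 groups, or about 4 of 80.

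Chromosome 14 was the first pattern: its genes stood lower in all 3 Tg hepatocyte pools and in 3 of 4 Tg liver pools. A trend with transcript length is argued against, since compared with genes matched in length the highest of the 3 hepatocyte pool medians was still -0.637. A change around one site, such as an insertion, is argued against by the 9 bins of 10 Mb with at least 10 genes, whose medians were all below 0 and at most -0.508. Fewer copies of the chromosome in a share of the cells is a candidate explanation, as a hypothesis: genes of low, middle and high expression would all be lowered alike, and the highest median of these classes was -0.695. Of the Tg liver pools, which were not cultured, 3 stood at -0.307 to -0.586, with the wild-type pools within 0.013 of 0. However, Tg liver pool 1 stood at 0.012 and the exact permutation p between the liver groups was 0.143. Other chromosomes of Tg livers moved by up to 0.282. The livers thus cannot decide whether culture was the whole cause in hepatocytes. Whether a loss of copies came with the label or with the parent line was not tested, and the RNA alone cannot show copy number. Other chromosomes shifted in Tg livers as well, alike in pools 3 and 4 (chromosome 15 by 0.239 and 0.146) and apart in pool 1 (chromosome 16 by -0.282), and their cause was not tested.

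Female and muscle transcripts in liver pools were the second. Wild-type C57BL/6J pool 2 held 934.8 CPM of Xist against 2.26 to 2.35 in the other wild-type pools and 0.198 CPM of the Y-linked Ddx3y (62.2 to 71.3 in the others), which is consistent with RNA of female mice in that pool. Muscle RNA may be there as well: 100% of 32 skeletal muscle markers, a list written after Acta1 had been seen, were highest in this pool of the 8 liver pools, and 3 of them exceed 1 CPM in the pools without the excess. The knockout pools could carry muscle RNA too, since their excess of the markers over C57BL/6NJ livers followed that of pool 2 across 31 markers (r = 0.973; genes are not independent replicates), at a median of 3.68% of its size; Ttn led pool 2 with 2747 CPM. Tissue next to the liver at dissection and a muscle programme within the liver stay open, and no biological explanation was tested for pool 2 because the labels give no sex.

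The 2 sets of CLIP libraries were the third. Within sets the lowest correlation of shares exceeded the highest between sets by 0.725. Depth is argued against: with every library thinned to 6151 counts the gap was 0.803. A few genes taking most of the counts are also argued against, since the gap was 0.664 without the 50 genes of highest share, with 26.0% to 39.8% of the counts left. The labels name no batch, protocol or fragment class that differs between the sets, so no biological explanation was tested and a difference in preparation stays open.

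Single values that stood apart were the following, in deposited CPM unless stated. Wild-type liver pool 2 had a total of 25320000 counts against 17040000 to 18130000, Ly6d at 1.86 (0.798 to 0.938), Kyat3 at 193.9 (155.3 to 157.3) and Acta1 at 777.6 (0.607 to 0.969). Wild-type liver pool 1 had A1cf at 278.7 (215.6 to 218.4), and wild-type liver pool 4 had Tff3 at 5.57 (2.49 to 2.85). Tg liver pool 1 had Acot1 at 2.19 (3.86 to 4.12), pool 2 Zc3h8 at 2.21 (1.41 to 1.497) and pool 4 Xist at 3.91 (2.91 to 3.00).

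The Tg effects in liver and hepatocytes differed for 131 genes, with Adgre5 at -4.65, Ndufa4l2 at 3.71, Prelp at -1.70, Fcna at -1.64, Cpne8 at 1.93 and Pfkp at 3.21 (log2). Chance is not excluded for that count, as 14 of 100 splits gave as many, with up to 2338. Of these, 10 (363 to 1556 genes) put hepatocyte Tg pools 1 and 2 and wild-type pool 1 against the other 3, the axis of transcript length and mitochondrial share that crosses the labels. Another 3 (816 to 2338) kept the hepatocyte pools by label and regrouped the liver pools or left them whole, and the one with 2338 tests the sum of the Tg effects. The Tg and knockout effects in liver differed for 167 genes, with A1cf at 2.46, Asns at 8.76, Meg3 at 5.04, Acot1 at -3.43, Ccdc171 at 2.48 and En2 at -8.74. Meg3 and En2 were too low to be tested in the Tg liver comparison itself. For that count 2 of 100 splits gave as many, the real one included, and the highest other gave 358. Such splits regroup the pools within both comparisons at once. They therefore test for no effect in either, and cannot decide whether the effects differ from each other.

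Among the 35 splits of the 8 livers of the Tg comparison, only the real one gave 188 genes (highest other 0) or 2 lists (highest other 1). A chance regrouping is thus an unlikely source of the 188 genes, though 35 splits do not exclude it. The 2 lists exceed the highest other by little, and 0 to 9 lists were called with 1 library out. For the CLIP list there chance is not excluded either: 23 of 35 splits gave a p as small as 0.675, the smallest being 0.000323. For CLIP over RNA, 1 of 100 splits, the real one, gave 33 genes (highest other 0). That split parts 2 assays, so it had to stand out and says nothing on the enriched genes. The 10 splits of 3 against 3 are too few for a share under 0.05. In hepatocytes the real values were 434 genes (highest other 0), 15 lists (0) and a CLIP list p of 0.011 (smallest other 0.0757), each reached by 1 of 10. In knockout livers they were 475 genes (0; 1 of 10), 0 lists (1; 10 of 10) and a CLIP list p of 0.65 (0.1; 8 of 10).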

How the results depend on the processing

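The alternatives that follow were chosen after seeing the data, as tests outside the plan: leaving out chromosome 14 genes, leaving these genes out of the overlaps, CLIP genes ranked within each set, the mitochondrial share as a covariate, and leaving out libraries for lists, overlaps and the CLIP ratio. Counts within 1.5 times of the reported one were those under RLE and upper-quartile scaling and the filter at 1 CPM in all 3 comparisons and both interactions. Where counts moved further, the cause was not tested. The fits without a library rest on fewer samples, which does not account for counts that rose, such as 4934 in hepatocytes without Tg pool 3. In hepatocytes the 434 genes became 2027 with DESeq2, 669 with no filter, 4323 in the fit of all 6 groups, 21 with the block, 259 with glmTreat, 283 without chromosome 14 genes, 3418 with the mitochondrial share, and 0 to 4934 with 1 library out. In Tg livers the 188 became 1242 with DESeq2, 96 with limma-voom, 991 in the fit of all 6 groups, 44 with the block, 71 with glmTreat, 64 with the mitochondrial share, and 27 to 561 with 1 library out. In knockout livers the 475 became 892 with DESeq2, 1079 with no filter, 42 in the fit of all 6 groups, 178 with glmTreat, and 137 to 645 with 1 library out. The liver minus hepatocyte count of 131 became 968 with DESeq2, 86 with no filter, 889 in the fit of all 6 groups, 18 with the block, and 5 to 3545; the Tg minus knockout count of 167 became 796 with DESeq2, 58 with the block, and 24 to 449.

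Lists called in hepatocytes (15) became 0 with an estimated correlation, 0 with the block and 2 to 13 with 1 library out. The 2 in Tg livers became 25 with the preset correlation, 0 with an estimated one, 1 with the block and 0 to 9; the 0 in knockout livers became 15 with the preset correlation and 1 with the block. Genes moving the same way in hepatocytes and Tg livers (31) numbered 1 at an adjusted p of 0.01, 150 at 0.1 and 274 with DESeq2, and opposite ones (1) numbered 0, 13 and 36. For hepatocytes and knockout livers the 17 same became 1, 95 and 105 and the 5 opposite 0, 51 and 53 (2 without chromosome 14 genes). For the liver comparisons the 9 same became 2, 47 and 76 (18 without wild-type pool 2) and the 4 opposite 1, 36 and 48 (9 without it). The 646 CLIP genes became 81 when seen in all 10 libraries, 5652 in at least 1, and 70 with at least 10 reads. The 33 enriched genes became 79 with total-count scaling and 18 to 37 with 1 library out. The p of the CLIP list in hepatocytes (0.011) was 0.282 and 0.167 with camera, and it turned up at 0.911 for the genes enriched over RNA. In Tg livers (0.675, down) it turned up at 0.686 for the 200 highest in the set of Itpripl2. In knockout livers (0.65, down) it turned up at 0.742 for 100 genes, 0.464 for 500, 0.557 for the 200 highest in the set of Pantr1 and 0.106 for enriched genes. A1cf in hepatocytes (0.02) ran from -0.17 to 0.144 with 1 library out, below 0 without Tg pool 3 (-0.04) and without wild-type pool 1 (-0.17).

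Named genes kept direction and side of the threshold in 127, 157 and 247 of 390, 304 and 366 fits with 1 library out (hepatocytes, Tg and knockout livers), lost the call in 261, 147 and 119, and reversed in the 2 fits of A1cf just given. The block ended the call of 52 of 64, 24 of 38 and 1 of 61 called genes, and DESeq2 that of none. With limma-voom 2, 13 and 20 calls ended, and in the fit of all 6 groups 8, 0 and 51. In simulated counts, true changes of 2-fold were recovered at 12.1% in hepatocytes, 43.1% in Tg livers and 72.3% in knockout livers, so a smaller change can be missed. False calls made up 12.3%, 7.45% and 11.2% of the calls there, above the nominal 5%. These shares hold for simulated counts, which lack the shifts that real pools share across genes. CLIP shares rest on at most 10902 counts per library, and a gene below 0.0275% to 0.0488% can go unseen.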

Other observations

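The tests of the last 2 paragraphs were chosen only after the results were seen, and they address patterns found in the same data. RNA of the substrain-specific gene Nnt, the mitochondrial transhydrogenase that is truncated in C57BL/6J mice, stood at 127 ± 3.81 CPM in knockout livers and 113 ± 9.87 in C57BL/6NJ livers (SD, n = 3 each). In the libraries labelled C57BL/6J the group means ran from 19.7 to 55.9 CPM. Entpd4 had no read in any of these 14 libraries, against 0.348 ± 0.0608 CPM in knockout and 0.368 ± 0.194 in C57BL/6NJ livers. Mitochondrially encoded RNA took 2.09% ± 1.204 of counts in Tg and 2.95% ± 0.865 in wild-type hepatocytes, 7.18% ± 1.16 in Tg and 5.85% ± 0.259 in C57BL/6J livers, and 4.82% ± 0.272 and 4.797% ± 0.345 in knockout and C57BL/6NJ livers. The Y-linked helicase gene Ddx3y ranged widely among hepatocytes, at 17.4 ± 19.8 CPM in Tg and 49.8 ± 29.0 in wild-type pools (TMM-scaled, n = 3 each), and was not called.

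Some genes known to respond to low oxygen were lower in Tg hepatocytes. Besides Ndufa4l2 and Pdk1, which raised the question, a list of 19 further tested genes written afterwards had 15 estimates below 0, with a median of -0.79, and 4 falls: the mitophagy receptors Bnip3 (-2.04) and Bnip3l (-1.74), the oxidoreductase gene Ero1l (-1.58) and Mxi1 (-0.85). Bnip3l and Ero1l lie on chromosome 14, where most genes were lower in these pools. fry gave p = 0.0393 and camera with an estimated correlation p = 0.209, and without the chromosome 14 members they gave p = 0.0626 and p = 0.287 (17 genes, 2 falls). Lower hypoxia signalling in the plated Tg cells stays a possibility that cannot be told apart from chromosome 14 and the wider shifts between these pools. In Tg livers fry gave p = 0.993, and in knockout livers the list was up at p = 0.0096 (p = 0.0792 with an estimated correlation).

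Gldn and Slc35f2, which rose in both Tg comparisons, lie on chromosome 9 with starts at 54286486 and 53771535. A change at one locus, such as an insertion, could raise both. The 25 genes that rose in both held 1 pair within 600 kb, and 2911 of 10000 random draws of as many tested genes held as many (p = 0.291). Tnfaip8l3 lies between the pair and was not called in either comparison (-0.60 and -0.65), so the test leaves the idea open without adding weight to it.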
